A study of Mus musculus with 31 samples.

How the data were processed

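Gene expression was measured by RNA sequencing in 31 libraries, each from the gastrocnemius muscle of a mouse. The mice were wild type or lacked MuRF1, the muscle ubiquitin ligase encoded by Trim63, were male or female, and ate chow or a high-fat diet. Per the labels' protocols, the high-fat diet held 45% fat from lard and was fed from 8 weeks of age, and the muscle was taken at 30 weeks. RNA with an integrity number above 8 was enriched for polyA transcripts, made into libraries with a stranded mRNA kit and sequenced on an Illumina HiSeq instrument with 150 bp paired-end reads, also per the labels' protocols.

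The authors deposited 1 table of raw read counts per library, with 39017 Ensembl gene identifiers each. Per the submitters' processing notes, bcl2fastq, featureCounts and the mouse build mm10 were used. The aligner, the annotation release and the strand setting of the counting are not given in the sources used here, so genes that overlap on opposite strands cannot be separated with certainty. Reads shared by near-identical copies of a gene may have been split or dropped in counting. Gene symbols were found for 37607 identifiers, and genes without one held 0.107% of the counts. Coordinates are those of mm10 from the GENCODE M21 annotation, which held 37693 of the identifiers.

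Libraries were grouped by their labels. In 19 records the animal number in the title differs from the animal number in the description. Where the group of the record's own title and the group of the title that carries the described animal differed, the library was put in no group. This held for 4 libraries, and 27 remained in 8 groups. For 1 further library, labelled male knockout high fat replicate 1, the described animal number is in no title, and it was kept in the group of its own title. The labels give different animal numbers, so libraries were taken as separate animals. Over 45 pairs of libraries with the same group in their titles, all 31 libraries included, the lowest chi-square per gene was 5.18 and 0 pairs were identical.

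Total counts ran from 9342028 to 14919379 per library, with mitochondrial genes holding 5.40% to 13.8% of them and the 10 most abundant genes 23.4% to 30.5%. A count of 3 corresponds to 0.201 to 0.321 CPM, the count divided by the total of the library and scaled by 10 to the power of 6. Counting intervals cover counting error only, since reads are not counted by molecule.

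Differences were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM scaling, a count filter with a minimum of 10 (filterByExpr), and robust dispersion. The model had 1 coefficient for each of the 8 groups and 1 spread shared by them. The filter left 13933 genes. The common dispersion of 0.019 corresponds to a variation of 13.8% between animals. The 15 contrasts were the genotype, diet and sex differences averaged over strata with equal weight, the single strata, and the 3 interactions. P-values were adjusted by Benjamini and Hochberg within each contrast at 0.05. A log2 fold change is given with its standard error after ±. The standard error was derived from the fold change and its F statistic. CPM per group are scaled by TMM, and CPM of a single library are not.

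The design, the contrasts, the gene lists, the rule for named genes and most of the alternatives were fixed before the data were examined. Named genes are Trim63, the 8 largest increases and decreases of each average contrast and the 5 largest of each other contrast among called genes with a mean log2 CPM of at least 0, up to 4 members of each list with the smallest p, and up to 5 genes with the smallest p within 10 Mb of Trim63. Genes with clone names were counted and passed over, not every gene that the rule names is printed, and genes of X and Y were ranked apart for sex. Of 35 lists with 777 genes, 34 were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry. They cover metabolic, contractile, proteolytic and signalling genes and markers of other cell types. The list of sex-linked genes served only to check labels.

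The steps were tested on simulated data with the real libraries' means and sizes, with 100 of the 13933 genes changed at each fold. The changed genes were drawn from those above a minimum mean count, so the shares do not cover genes of low count. For the average genotype contrast 86% of genes changed 1.5-fold and 99% of genes changed 2-fold were called. The shares were 51% and 85% for genotype in male chow, 39% and 81% for genotype in female chow, 43% and 79% for diet in wild-type females, and 39% and 78% for the sex-by-diet interaction. A simulated trend with GC content gave 1997 calls for that interaction, and the correction left 0. Of 34 lists, the 1 that had been shifted was called and 0 others were. Genes were drawn independently of each other, so this does not test camera on lists whose genes vary together.

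Alternatives were DESeq2 1.42.0 size factors and its Wald test, no count filter, a stricter filter, a replicate block, all 31 libraries grouped by title or by animal number, fits to the compared groups alone, omission of genes within 10 Mb of Trim63, and omission of each library in turn. Added after the data were seen were corrections for transcript GC content and length, 30 libraries grouped by animal number, omission of 3 libraries with Krt10 above 10 CPM, omission of 3 libraries with Trim63 between 50 and 150 CPM, and the lists of single strata without each library in turn. Other splits of the libraries were limited to 40 draws for contrasts over all groups.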

Results

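Gastrocnemius muscle of mice with and without MuRF1 was compared across sex and diet. Of 31 libraries, 27 had 1 group by their labels. These were 4 each of male wild type chow, male knockout chow and male wild type high fat, and 3 each of male knockout high fat, female wild type chow, female knockout chow, female wild type high fat and female knockout high fat. Total counts per library ran from 9342028 to 14919379. The series asks how MuRF1 loss, sex and a high-fat diet shape the muscle transcriptome.

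Trim63 (ENSMUSG00000028834, chromosome 4, 134315120 to 134329629, mm10), which encodes MuRF1, was measured first because it checks the genotype labels. It lay between 183.3 and 253.61 CPM in 12 of the 14 wild-type libraries, at 108.54 and 130.09 CPM in male wild type chow 3 and female wild type chow 2, and between 0.47 and 6.24 CPM in 12 of the knockout libraries. The library labelled male knockout high fat replicate 1 held 107.11 CPM, which goes against its label. Trim63 was lower in knockouts by edgeR in male chow (log2 fold change -6.19 ± 1.06, adjusted p = 0.00299) and in female high fat (-7.56 ± 1.37, adjusted p = 0.0253). In female chow it was -7.24 ± 1.34 (adjusted p = 0.0603) and in male high fat -2.68 ± 0.92 (adjusted p = 0.33), neither of which passed the threshold. Without the library labelled male knockout high fat replicate 1 the male high-fat value was -8.23 (adjusted p = 6.09e-06), and without female wild type chow replicate 2 the female chow value was -7.43 (adjusted p = 0.039). Without these and male wild type chow 3, the 3 grouped libraries with Trim63 between 50 and 150 CPM, the 2 values were -8.25 (adjusted p = 3.38e-07) and -7.43 (adjusted p = 1.76e-07). The female high-fat call was lost without any 1 of 5 of the 6 libraries, with adjusted p from 0.0542 to 0.125. Ddx3y, a Y-linked gene, lay between 30.29 and 55.76 CPM in males and between 0 and 0.76 CPM in females, and Xist, the X inactivation RNA, between 67.65 and 270.88 CPM in females and between 0 and 1.44 CPM in males.

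**Figure D1:**
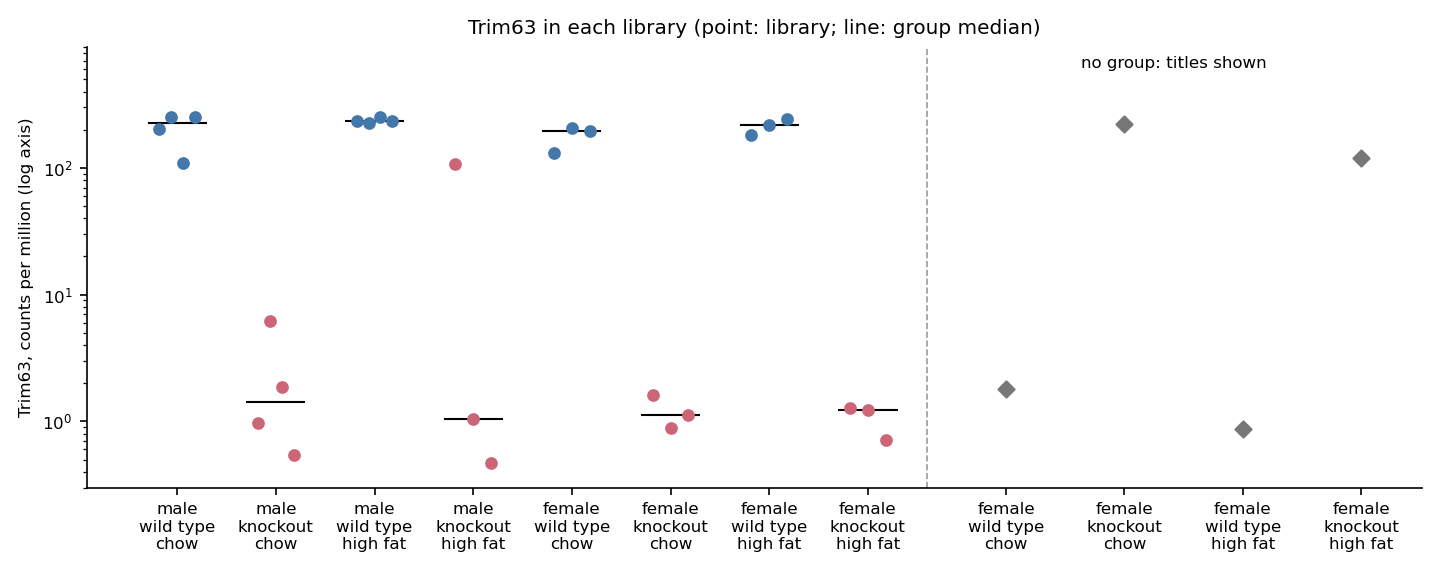
Trim63 in each library in CPM on a log axis, with blue points for wild type, red for knockout and a line at the group median. The red point at 107.11 is the library labelled male knockout high fat replicate 1, and the 4 grey diamonds are libraries put in no group, placed by their titles.

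On average over sex and diet, knockout muscle held less mRNA of extracellular matrix genes, most of all in males on chow, and of several genes close to Trim63. The average contrast called 737 genes, of which 331 were higher and 406 lower in knockouts, and 44 changed at least 2-fold. After Trim63 (-5.92 ± 0.60), the largest decreases were Rab6b (-3.62 ± 0.45), Fbxo44 (-2.19 ± 0.30), the cell-cycle regulator E2f2 (-1.68 ± 0.17), Zfp984 (-1.65 ± 0.27), Sfn (-1.62 ± 0.27), Dcdc2b (-1.50 ± 0.16) and Paqr7 (-1.26 ± 0.12). The largest increases were Zfp992 (2.81 ± 0.31), Eno1b (2.18 ± 0.32), Rbp7 (1.68 ± 0.31), Hyi (1.03 ± 0.22), Ncmap (0.86 ± 0.25), Odf3l2 (0.79 ± 0.15), Rps19-ps3 (0.74 ± 0.20) and Angptl7 (0.73 ± 0.20). Of these, 6 of the 7 decreases after Trim63 and 6 of the 8 increases lie on chromosome 4 within 25 Mb of Trim63, and Rab6b, Eno1b and Odf3l2 lie elsewhere. Eno1b shares 99.5% of 1652 bases with Eno1, a gene of chromosome 4, so its value is uncertain.

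Of 35 extracellular matrix genes, 20 fell, 0 rose and 15 were not called, and 29 fell when adjusted over the list alone. The gelatinase Mmp2 (-0.63 ± 0.11) and the collagens Col6a2 (-0.60 ± 0.12), Col5a1 (-0.57 ± 0.12) and Col6a1 (-0.52 ± 0.11) led them. Camera called the list lower (adjusted p = 1.72e-23), and not so with adjusted p = 0.264 with an estimated correlation. Of 16 fibroblast markers 6 fell, among them Smoc2 (-0.35 ± 0.07), Pi16 (-0.42 ± 0.09) and Col1a1 (-0.80 ± 0.19), and 13 fell adjusted over the list alone. The camera call was lost with adjusted p = 0.264 with an estimated correlation. Of 21 macrophage markers 7 fell, with Ctss at -0.43 ± 0.10, C1qa at -0.37 ± 0.10 and Csf1r at -0.39 ± 0.10, and 11 fell adjusted over the list alone, with adjusted p = 0.316 with an estimated correlation. Of 13 polyamine genes 3 rose, namely the spermine synthase gene Sms (0.34 ± 0.06), Amd1 (0.35 ± 0.07) and Odc1 (0.44 ± 0.10), with 3 adjusted over the list alone and adjusted p = 0.316 with an estimated correlation. In male chow 27 matrix, 14 fibroblast and 12 macrophage genes were called lower, and 0 of each list in male high fat, female chow and female high fat. Library scores were not used as a term for genotype. A different share of these cells in the samples and a genotype effect therefore cannot be told apart. The medians were lowest in male chow. They were -1.021 in male chow, -0.519 in male high fat, -0.095 in female chow and -0.334 in female high fat for matrix genes, -0.790, -0.339, -0.062 and -0.050 for fibroblast markers, and -1.077, -0.343, -0.046 and 0.020 for macrophage markers. By camera the genotype effect on all 3 lists differed between the sexes, with median differences of 0.537, 0.506 and 0.613 (adjusted p = 4.22e-18, 3.52e-13 and 3.52e-13), and not so with adjusted p = 0.251 with an estimated correlation. Fry called 0 lists for this difference.

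Of 26 denervation and neuromuscular junction genes, Musk rose (0.55 ± 0.14) and 4 fell, among them Ncam1 (-0.45 ± 0.11) and Ache (-0.35 ± 0.09), with adjusted p = 0.137 with an estimated correlation. Of 20 clock genes 4 rose, including Hlf (0.35 ± 0.08) and Usp2 (0.40 ± 0.10), and 5 rose and 1 fell adjusted over the list alone, with adjusted p = 0.422 with an estimated correlation. Of 27 ubiquitin ligase genes, Wwp1 rose (0.22 ± 0.07) and Trim62 fell (-0.65 ± 0.19). Among 34 proteasome genes 0 were called.

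Grouping all 31 libraries by title includes the 4 put in no group, whose Trim63 or Ddx3y goes against their titles. The average genotype count depended on the libraries used. It was 134 with all 31 libraries grouped by title, 85 without the 3 libraries high in Krt10, and 317, 361, 410, 435, 458, 469, 476 and 477 without female wild type chow 4, male knockout high fat 3, female knockout chow 2, female wild type high fat 4, male knockout chow 2, female knockout chow 3, male wild type chow 2 and male wild type high fat 2, and 1164 without male wild type chow 4.

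Genes near Trim63 were called more often than others. Within 10 Mb of Trim63, 43 of 245 tested genes were called, Trim63 included. Leaving Trim63 out, 19 of 78 genes within 2 Mb (24.4%), 23 of 166 at 2 to 10 Mb (13.9%) and 44 of 240 at 10 to 25 Mb (18.3%) were called, against 20 of 377 on the rest of chromosome 4 (5.31%) and 627 of 12960 on other chromosomes (4.84%). The odds ratio against other chromosomes was 3.89 for 2 to 25 Mb (95% interval 2.91 to 5.13, Fisher's exact test, two-sided, p = 1.57e-17), although neighbouring genes are not independent. The genes of smallest p were the histone deacetylase gene Hdac1 (chromosome 4, 129516104 to 129542713, -1.03 ± 0.07), Paqr7, Zfp46 (-1.005 ± 0.097), Hmgn2 (-0.90 ± 0.09) and E2f2. Hdac1 was 10.7 ± 1.02 CPM (SD, n = 4) in male wild type chow and 3.90 ± 0.504 CPM (SD, n = 4) in male knockout chow.

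**Figure D2:**
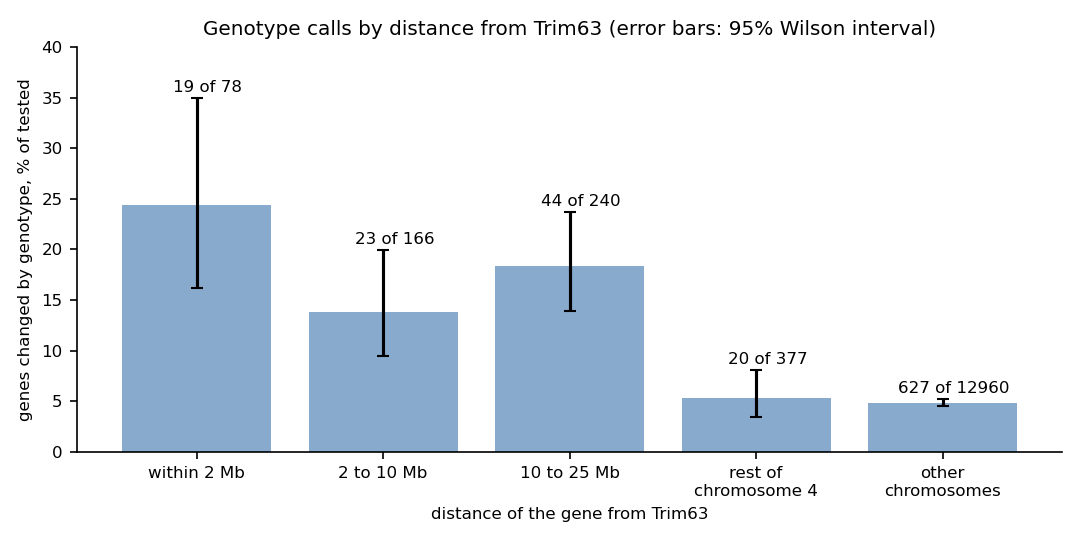
Percent of tested genes called in the average genotype contrast by their distance from Trim63, with 95% Wilson intervals as error bars and called of tested genes above each bar. The 3 bars within 25 Mb stand at 24.4%, 13.9% and 18.3%, above 5.31% on the rest of chromosome 4 and 4.84% elsewhere.

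In males on chow, knockout libraries held less mRNA of matrix, macrophage and interferon genes and more of glucocorticoid-responsive genes. Here 1011 genes were called, 297 higher and 714 lower (n = 4 and 4), and 1528 with wild type 4 and knockout 4 exchanged. Knockout 1, 2 and 3 had the lowest matrix scores of the 31 libraries (mean log2 CPM 4.085, 3.482 and 3.935), and wild type 4 (4.766) lay below knockout 4 (4.935). A different share of matrix-forming and other non-muscle cells in these libraries was not tested. The largest decreases after Trim63 were Rab6b (-4.27 ± 0.86), Mycn (-2.86 ± 0.83), Sfn (-2.40 ± 0.54) and the hyaluronan synthase gene Has2 (-2.37 ± 0.58). The largest increases were Zfp992 (3.26 ± 0.58), the mTORC1 inhibitor gene Ddit4 (2.31 ± 0.54), Eno1b (2.11 ± 0.59), Arrdc2 (2.05 ± 0.60) and Chac1 (1.98 ± 0.52). Of 35 matrix genes 27 fell, led by Mmp2 (-1.17 ± 0.21), Col14a1 (-1.42 ± 0.28) and Col6a3 (-1.22 ± 0.24), and 33 fell adjusted over the list alone, with adjusted p = 0.117 with an estimated correlation. Of 21 macrophage markers 12 fell, among them Ctss (-1.30 ± 0.21) and Csf1r (-1.10 ± 0.20), and 19 fell adjusted over the list alone, with adjusted p = 0.115 with an estimated correlation. Of 16 fibroblast markers 14 fell, and 16 adjusted over the list alone, with adjusted p = 0.115 with an estimated correlation, and of 18 endothelial markers 8 fell, and 13 adjusted over the list alone, with adjusted p = 0.218 with an estimated correlation. Of 31 interferon genes 13 fell, with Oas2 at -1.16 ± 0.25 and Gbp7 at -1.06 ± 0.24, and 24 fell adjusted over the list alone, with adjusted p = 0.115 with an estimated correlation. Of 19 glucocorticoid targets 10 rose, with Tsc22d3 at 0.87 ± 0.13, Sgk1 at 0.74 ± 0.14 and the glutamine synthetase gene Glul at 1.52 ± 0.29, and 12 rose adjusted over the list alone, with adjusted p = 0.115 with an estimated correlation. Without knockout 2 the genes called lower were 10 of the matrix, 5 macrophage and 3 interferon genes, without wild type 3 they were 6 fibroblast genes, with 5 glucocorticoid targets higher, and without wild type 2 they were 0 endothelial genes by edgeR. Of 14 satellite cell markers, Heyl (-1.001 ± 0.195) and Myod1 (-1.002 ± 0.197) fell. Every omission of 1 of the 8 libraries moved the count by over 1.5 times, to 350, 489 and 590 without wild type 3, 1 and 2, to 224, 415 and 481 without knockout 2, 3 and 1, and to 1852 and 1680 without wild type 4 and knockout 4. It was 306 in a fit to these 2 groups alone, 501 with all libraries grouped by title, and 290 without the 3 libraries with Trim63 between 50 and 150 CPM.

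In the other strata few genes were called, and several of the named ones, such as Hdac1, Paqr7 and Hmgn2, lie on chromosome 4 within 10 Mb of Trim63. In males on the high-fat diet (n = 4 and 3, with the library labelled male knockout high fat replicate 1 among the 3), 7 genes were higher and 12 lower. E2f2 (-2.41 ± 0.35), Uchl1 (-1.89 ± 0.35), Mybph (-1.84 ± 0.26), Paqr7 (-1.63 ± 0.24), Ndufs5 (-1.32 ± 0.19) and Hdac1 (-1.08 ± 0.14) fell, and Zfp992 (4.08 ± 0.70), the folate enzyme gene Mthfd2 (1.15 ± 0.20), Ppt1 (0.61 ± 0.13), Fbxo6 (0.61 ± 0.12) and Lpin1 (0.58 ± 0.11) rose. In females on chow (n = 3 and 3) Adgrb2 (-1.74 ± 0.33), Ndufs5 (-1.08 ± 0.19), Hmgn2 (-0.99 ± 0.19) and Hdac1 (-0.77 ± 0.14) fell. The clone-named pseudogene BC002163 of chromosome 16, given for this reason alone, shares 99.4% of 319 bases with Ndufs5. It rose by 3.84 in the average genotype contrast, where Ndufs5 fell (-1.02), so the Ndufs5 values are uncertain. Without female wild type chow 2 and the other 2 libraries with Trim63 between 50 and 150 CPM, 17 genes were called. The fifth gene, Capn11, was higher (4.13) and falls outside the rule for named genes by its low level and was chosen after its values were seen. In females on the high-fat diet (n = 3 and 3) 14 genes were higher and 20 lower, with Nmrk2 (1.30 ± 0.23), Slc30a2 (1.13 ± 0.24) and Kcnab1 (1.08 ± 0.22) up and Fbxo44 (-3.75 ± 0.74), Dcdc2b (-2.32 ± 0.35), Adgrb2 (-2.23 ± 0.34), Paqr7 (-1.38 ± 0.24) and Zfp46 (-1.37 ± 0.21) down. Sms (0.65 ± 0.12) and Amd1 (0.68 ± 0.15) rose among 13 polyamine genes, with neither called without wild type high fat 4, and 0 of 35 matrix genes were called, with 0 adjusted over the list alone. Without genes within 10 Mb of Trim63 the counts were 7 in male high fat, 0 in female chow and 0 in female high fat, where 491 and 1907 genes of the female strata had unadjusted p under 0.05 in edgeR. DESeq2, run with these genes included, called 54, 11 and 194. Leaving out 1 library gave 6, 8 and 10 genes in male high fat without wild type 3, 1 and 2, 8 and 8 without knockout 2 and 3, and 83 without wild type 4. In female chow it gave 0 without wild type 3 or 4 or knockout 4 (368, 633 and 386 at unadjusted p under 0.05 in edgeR), 1 without knockout 2 or 3, and 17 without wild type 2. In female high fat it gave 3, 8 and 14 without knockout 3, 4 and 2 and 7 and 9 without wild type 4 and 3.

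The genotype effect was tested against diet and sex directly. Its difference between diets was called for 3 genes. Mid1ip1, a regulator of lipid synthesis (-1.49 ± 0.24, adjusted p = 0.0153), the actin-filament gene Lmod2 (-0.997 ± 0.170, adjusted p = 0.0177) and the small heat shock gene Hspb7 (-0.96 ± 0.18, adjusted p = 0.0442), which lies on chromosome 4 within 10 Mb of Trim63, had a lower knockout-to-wild-type ratio on the high-fat diet than on chow by edgeR. Mid1ip1 was 12.2 ± 1.17 CPM (SD, n = 4) in male wild type chow and 30.6 ± 9.92 CPM (SD, n = 4) in male knockout chow. The difference between sexes was called for Adgrb2 alone in edgeR (-2.75 ± 0.39, adjusted p = 0.00132), a gene of chromosome 4 within 10 Mb of Trim63 (129984870 to 130022633). Counts at unadjusted p under 0.05 were 1188 and 1147. The 3 calls were lost without female wild type chow 4 or female knockout chow 3, and DESeq2 called 46 and 16 genes.

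The diet effect averaged over the 4 groups was called for few genes. The average diet contrast called 57 genes, 50 higher and 7 lower on the high-fat diet, with 0 changed 2-fold. Among the largest increases were Kif26b (0.83 ± 0.16), Npnt (0.77 ± 0.12), the Notch ligand gene Dll1 (0.76 ± 0.16), the spermine oxidase gene Smox (0.65 ± 0.11), Plekho1 (0.56 ± 0.10), Myod1 (0.55 ± 0.10) and Sbk2 (0.53 ± 0.08). The decreases were Pla2g5 (-0.80 ± 0.17), Fnip1 (-0.39 ± 0.09), Ccdc50 (-0.35 ± 0.06), Cbfb (-0.30 ± 0.06), Stxbp3 (-0.28 ± 0.06), Celf2 (-0.26 ± 0.06) and Sesn1 (-0.25 ± 0.06). Of 25 glycolysis and glycogen genes, Gys1 (0.22 ± 0.05) and Pfkm (0.25 ± 0.06) rose, 11 rose and 2 fell adjusted over the list alone, with adjusted p = 0.611 with an estimated correlation. Gpx1 (0.36 ± 0.06) and Hmox1 (0.34 ± 0.08) rose among the antioxidant genes. The count was 2 after a GC correction, 2 without the 3 libraries high in Krt10, 2 without the 3 libraries with Trim63 between 50 and 150 CPM, 0 with all 31 libraries grouped by title (1529 at unadjusted p under 0.05 in edgeR), and 327 in DESeq2. It was 25, 26, 28, 29, 32, 34, 34, 36 and 36 without female wild type chow 2, female knockout chow 2, male knockout high fat 1, female wild type chow 4, female wild type high fat 4, female knockout chow 4, female knockout high fat 3, male wild type chow 1 and male knockout chow 3, and 94, 145 and 335 without male knockout high fat 3, male wild type chow 2 and female wild type high fat 2.

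In wild-type males the high-fat diet lowered Angptl4, Pdk4 and a few other fatty acid oxidation genes. Of 65 called genes, 30 were higher and 35 lower (n = 4 and 4). The lipase inhibitor gene Angptl4 (-2.52 ± 0.38), the pyruvate dehydrogenase kinase gene Pdk4 (-1.99 ± 0.37), the receptor gene Chrna2 (-1.92 ± 0.44), the thioesterase gene Acot2 (-1.46 ± 0.15) and March4 (-1.34 ± 0.32) fell most. Cyp2f2 (2.53 ± 0.46), Sfrp2 (2.51 ± 0.54), Slc15a5 (2.49 ± 0.29), the adipocyte gene Cfd (2.11 ± 0.28) and Cyp2e1 (2.04 ± 0.42) rose most. Of 36 fatty acid oxidation genes 4 fell and 32 were not called, and 12 fell adjusted over the list alone, with adjusted p = 0.442 with an estimated correlation. The tendon marker Comp rose (1.29 ± 0.27). The count was 22 to 38 without male wild type chow 2 (22), male wild type high fat 1 (24), 3 (25) and 2 (38) or male wild type chow 1 (27), and 167 in DESeq2. It was 98, 104 and 161 after GC, length and both corrections and 1 with all 31 libraries grouped by title. Without male wild type chow 1, 2 fatty acid oxidation genes were called.

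In knockout males high-fat libraries held less mRNA of oxidative and contractile genes and more of matrix and macrophage genes than the chow libraries. Of 1618 called genes, 995 were higher and 623 lower (n = 4 and 3, with the library labelled male knockout high fat replicate 1 among the 3). Socs1 (4.29 ± 1.21), the immunoglobulin gene Igkc (4.05 ± 0.87), Trim63 (3.70 ± 1.08, and -1.85 without that library), Cyp2e1 (3.26 ± 0.48) and Sfrp2 (3.15 ± 0.76) rose most, and Chrna2 (-2.78 ± 0.53), Calm4 (-2.75 ± 0.84), Acot1 (-2.66 ± 0.58), Depp1 (-2.55 ± 0.57) and Ddit4 (-2.47 ± 0.61) fell most. Of 36 fatty acid oxidation genes 17 fell, among them Acot2 (-1.42 ± 0.17), Ech1 (-0.96 ± 0.17) and Fabp3 (-1.81 ± 0.34), and 22 fell adjusted over the list alone, with adjusted p = 0.301 with an estimated correlation. Of 48 oxidative phosphorylation genes 12 fell, with Cox5b at -0.65 ± 0.16, and 29 fell adjusted over the list alone, with adjusted p = 0.36 with an estimated correlation. Of 35 matrix genes 17 rose, with Dcn at 1.29 ± 0.26 and Lox at 1.51 ± 0.33, and 23 rose adjusted over the list alone, with adjusted p = 0.338 with an estimated correlation. Of 21 macrophage markers 12 rose, with Ctss at 1.17 ± 0.23, and 16 rose adjusted over the list alone, with adjusted p = 0.295 with an estimated correlation. The chow libraries of this comparison include the 3 of lowest matrix and macrophage scores. Without high fat 2 the called genes were 7 for fatty acid oxidation, 0 for oxidative phosphorylation by edgeR, 2 for matrix and 3 for sarcomere, and without chow 2 they were 5 for macrophage. The growth factor gene Igf1 (1.93 ± 0.21) and the insulin receptor substrate genes Irs1 (1.52 ± 0.28) and Irs2 (1.22 ± 0.21) rose, and 8 of 26 sarcomere genes fell, including Lmod2 (-0.89 ± 0.17) and Acta1 (-0.58 ± 0.13), with 9 adjusted over the list alone and adjusted p = 0.295 with an estimated correlation. The count was 375, 702 and 965 without knockout high fat 2, 1 and 3, 571, 722 and 813 without knockout chow 2, 1 and 3, 648 without the 3 libraries with Trim63 between 50 and 150 CPM, and 3188 in a fit to these 2 groups alone.

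In wild-type females high-fat libraries held more mRNA of oxidative genes and less of tendon markers than the chow libraries. Of 2101 called genes, 1223 were higher and 878 lower (n = 3 and 3). Xlr3a (2.88 ± 0.79), the lipid-droplet gene Cidea (2.58 ± 0.51), Myh3 (1.75 ± 0.57), Acot1 (1.73 ± 0.58) and Sln (1.70 ± 0.54) rose most, and Mup10 (-3.98 ± 0.73), the Wnt inhibitor gene Wif1 (-3.12 ± 0.48), Sema3d (-2.48 ± 0.62), Cyp2e1 (-2.33 ± 0.45) and the tendon transcription factor gene Mkx (-2.32 ± 0.49) fell most. Of 36 fatty acid oxidation genes 19 rose, including Acot2 (0.97 ± 0.18), Crat (0.51 ± 0.10) and Ech1 (0.85 ± 0.18), and 20 rose adjusted over the list alone, with adjusted p = 0.578 with an estimated correlation. Of 48 oxidative phosphorylation genes 19 rose, with Cyc1 at 0.59 ± 0.13, and 23 rose adjusted over the list alone, with adjusted p = 0.712 with an estimated correlation. Without chow 4 the medians of these lists went from 0.517 to 0.368 and from 0.345 to 0.222, with 3 and 2 genes called. Of 15 tendon markers 8 fell, with Kera at -2.18 ± 0.45, and 11 fell adjusted over the list alone, with adjusted p = 0.578 with an estimated correlation, and 3 were called without chow 4. Of 18 endothelial markers 9 rose, and 4 of 16 Schwann cell and 4 of 21 macrophage markers fell, with the same numbers adjusted over the list alone and all 3 with adjusted p = 0.712 with an estimated correlation. Without high fat 4, 0 endothelial markers were called by edgeR, and without chow 4 the called genes were 0 Schwann cell and 1 macrophage marker. High fat 4 had a GC slope of 0.666 per 10 points and 5.4% mitochondrial counts, the lowest share of the 31 libraries. Over genes, the fold changes correlated with transcript GC content (Spearman's rho = 0.641), and 140 genes were called after a GC correction. With each library's mean log2 CPM over the tendon markers (the tendon score) as a further term, 103 genes were called. In its place the slow-fibre score gave 685 genes, oxidative phosphorylation 711, macrophage 1332, endothelial 1758, fibroblast 1997, matrix 2040 and adipocyte 2123. The count was 150, 607 and 1100 without high fat 4, chow 4 and chow 2, 321 without the 3 libraries high in Krt10, 848 without the 3 libraries with Trim63 between 50 and 150 CPM, 5 with all 31 libraries grouped by title, 743 in a fit to these 2 groups alone, and 3656 with all 31 libraries grouped by animal number.

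In knockout females high-fat libraries differed in clock genes and held more mRNA of oxidative and proteasome genes than the chow libraries. The oxidative and proteasome genes stood highest in 1 of the 3 high-fat libraries. Of 2758 called genes, 1548 were higher and 1210 lower (n = 3 and 3). The clock genes Npas2 (3.08 ± 0.71), Arntl (2.11 ± 0.45) and Nfil3 (1.79 ± 0.35), the hormone gene Erfe (2.58 ± 0.58) and Pdk4 (2.04 ± 0.43) rose most. The largest decreases were Dsp (-9.57 ± 2.51), Dmkn (-6.50 ± 1.64), S100a8 (-5.32 ± 1.42), S100a9 (-5.12 ± 1.31) and Krt10 (-3.71 ± 0.92), which are skin and neutrophil genes. On chow Dsp stood at 8.25, 0 and 17.85 CPM in replicates 2, 3 and 4 and S100a8 at 27.52, 0.65 and 0.32 CPM. Dsp was 0 in the 3 high-fat libraries, so its fold has no measured high-fat level. Krt10 stood at 22.38 and 47.38 CPM in female knockout chow 2 and 4, at 23.75 CPM in female wild type chow 4 and at 0.81 to 2.82 CPM in the other libraries. Of 48 oxidative phosphorylation genes 30 rose, with Ndufb7 at 0.92 ± 0.19, and 41 rose adjusted over the list alone, with adjusted p = 0.527 with an estimated correlation. Of 34 proteasome genes 19 rose, with Psmb5 at 0.66 ± 0.15, and 26 rose adjusted over the list alone, with adjusted p = 0.527 with an estimated correlation. Over these 48 and 34 genes high fat 3 had mean log2 CPM of 8.615 and 7.059, against 8.001 and 6.607 in high fat 2 and 8.023 and 6.634 in high fat 4. Without high fat 3 the medians went from 0.497 to 0.271 and from 0.383 to 0.227, and 0 of either list were called by edgeR. Asb2 (1.21 ± 0.19) and Fbxo32 (1.08 ± 0.18) were among 5 of 27 ubiquitin ligase genes that rose, while 1 fell and the list median was -0.059. Without high fat 3, 2 ligase genes were called higher and 0 lower. Of 20 clock genes 5 rose and 10 fell, with Cry1 at 0.85 ± 0.14, Hlf at -1.10 ± 0.18 and Per3 at -1.49 ± 0.24, and 5 rose and 11 fell adjusted over the list alone, with adjusted p = 0.527 with an estimated correlation. Of 15 tendon markers 11 fell and of 17 adipocyte markers 9 fell, among them Prg4 (-1.69 ± 0.33) and Pck1 (-3.16 ± 0.53), and 12 and 9 fell adjusted over the list alone, both with adjusted p = 0.527 with an estimated correlation. Without high fat 3 the called genes were 3 for tendon and 4 higher and 4 lower for the clock, and without chow 4 they were 3 for adipocytes. The count was 3 without the 3 libraries high in Krt10, which leaves 1 female knockout chow library assumed to vary like the others, and 414, 1034, 1142 and 1661 without high fat 3, chow 4, chow 2 and chow 3. It was 1514 in a fit to these 2 groups alone and 10 with the tendon score as a further term. Other scores gave 133 (oxidative phosphorylation), 301 (adipocyte), 1196 (matrix), 1469 (macrophage), 2168 (fibroblast), 2772 (slow fibre) and 2825 genes (endothelial).

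Female and male muscle differed in the diet effect for many genes. The sex-by-diet interaction called 6206 of 13933 genes, 3204 with a higher and 3002 with a lower diet effect in females than in males. Chrna2 (3.86 ± 0.55), Acot1 (3.84 ± 0.57), Pdk4 (3.38 ± 0.41), Cidea (3.14 ± 0.48) and Angptl4 (3.06 ± 0.40) lay highest, and Mup10 (-6.71 ± 1.19), Dmkn (-6.25 ± 2.08), Cyp2e1 (-5.49 ± 0.45), Sfrp2 (-4.14 ± 0.56) and Pon1 (-4.09 ± 0.52) lowest. Dmkn, a skin gene, stood at 6.88, 7.07 and 13.93 CPM in the 3 female chow libraries high in Krt10 and at 0 to 0.42 CPM in the others. Pdk4 fell from 1227 ± 332 CPM (SD, n = 4) on chow to 309 ± 28.2 CPM (SD, n = 4) on the high-fat diet in wild-type males. In wild-type females its means were 281 ± 196 CPM (SD, n = 3) on chow and 748 ± 223 CPM (SD, n = 3) on the high-fat diet. Cyp2e1 fell from 59.5 ± 21.8 CPM (SD, n = 3) to 5.83 ± 0.472 CPM (SD, n = 3) in knockout females and rose from 2.11 ± 0.83 CPM (SD, n = 4) to 20.6 ± 5.17 CPM (SD, n = 3) in knockout males.

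**Figure D3:**
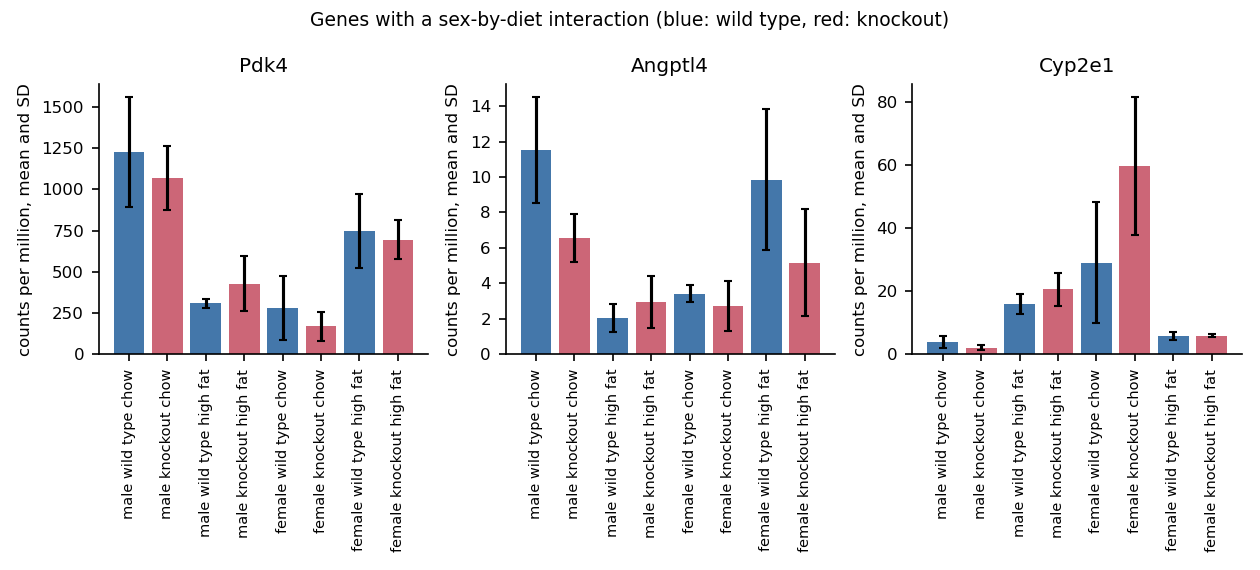
Mean CPM of Pdk4, Angptl4 and Cyp2e1 in the 8 groups, with blue bars for wild type, red bars for knockout and error bars of 1 SD over 3 or 4 libraries. Pdk4 stands at 1227 in male and 281 in female wild type chow, and at 309 and 748 on the high-fat diet.

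By group, 43 of 48 oxidative phosphorylation genes had a higher diet effect in females, including Cox5b (1.02 ± 0.16) and Ndufs7 (0.97 ± 0.15), and 44 were higher and 1 lower adjusted over the list alone, with adjusted p = 0.508 with an estimated correlation. Of 36 fatty acid oxidation genes 27 were higher, with Acot2 at 2.45 ± 0.17 and Ech1 at 1.39 ± 0.17, and 28 adjusted over the list alone, with adjusted p = 0.508 with an estimated correlation. Of 15 tendon markers 12 were lower, with Fmod at -1.99 ± 0.26 and Comp at -2.03 ± 0.28, and 12 adjusted over the list alone, with adjusted p = 0.508 with an estimated correlation. Of 35 matrix genes 21 were lower and 1 higher, with Col14a1 at -2.10 ± 0.27, and 23 and 1 adjusted over the list alone, with adjusted p = 0.57 with an estimated correlation. Of 21 macrophage markers 15 were lower, with Cd163 at -1.38 ± 0.18, and of 27 lipid synthesis genes 18 were lower and 3 higher, with Fads1 at -1.42 ± 0.20. Both lists had adjusted p = 0.508 with an estimated correlation. Igf1 (-2.42 ± 0.21) and Igf1r (-1.55 ± 0.23) were lower and the heat shock co-chaperone gene Bag3 higher (1.18 ± 0.12). Fit within each genotype, the interaction was called for 1405 genes in wild types and 5210 in knockouts, with 1094 in both and 2 of these in opposite directions. Without the 3 libraries high in Krt10 it was called for 3901 genes.

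**Figure D4:**
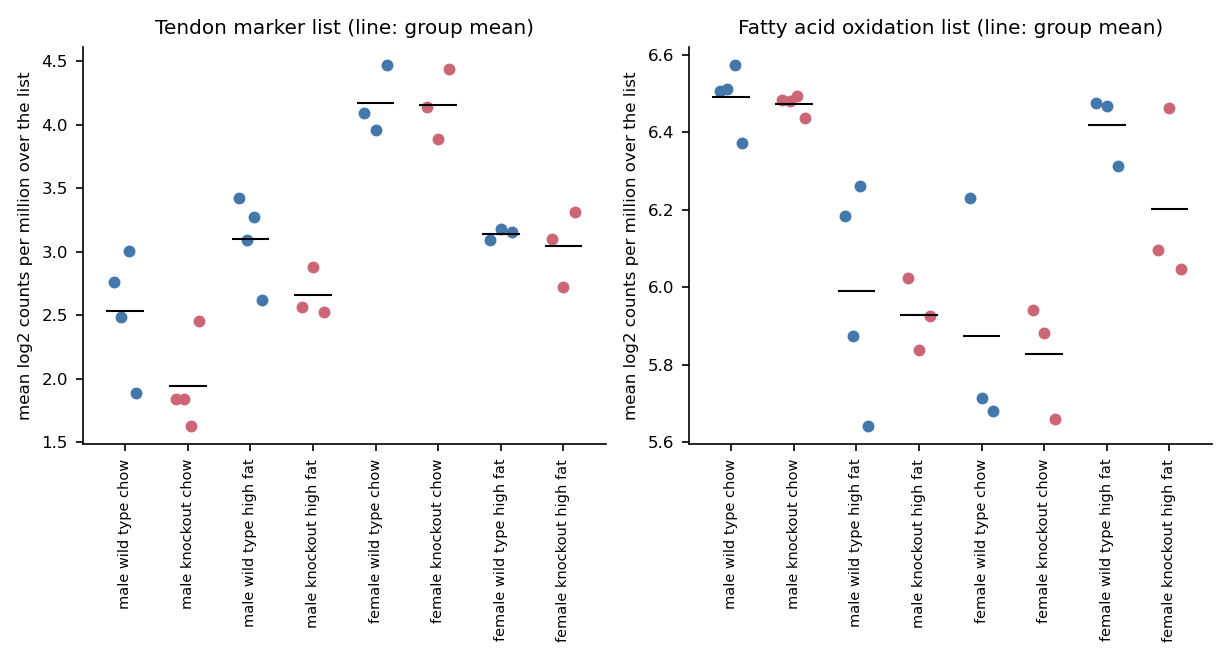
Mean log2 CPM over the tendon markers and over the fatty acid oxidation genes in each library, with blue points for wild type, red for knockout and a line at the group mean. On both lists the female chow groups stand apart from the male chow groups, higher for tendon markers and lower for fatty acid oxidation.

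On average more genes were called for sex than for genotype or diet. Of 4738 called genes, 2234 were higher and 2504 lower in females, and 4583 of 13462 autosomal genes were called when tested alone. Among autosomal genes Mup10 (4.20 ± 0.62), the adrenergic receptor gene Adrb3 (2.64 ± 0.26), the cardiac actin gene Actc1 (2.49 ± 0.15), Mycn (2.44 ± 0.30), Mybph (2.40 ± 0.12), Retn (2.11 ± 0.19), Pla2g5 (2.06 ± 0.16) and Ngfr (2.03 ± 0.27) were highest in females. Slc15a5 (-4.93 ± 0.24), Irx3os (-3.77 ± 0.29), Actr3b (-3.51 ± 0.11), Kcnf1 (-3.32 ± 0.28), Cacna2d4 (-3.26 ± 0.18), Amd1 (-3.14 ± 0.08), Amd-ps3 (-3.13 ± 0.26) and Amd2 (-3.09 ± 0.12) were lowest. Amd1, which encodes S-adenosylmethionine decarboxylase of polyamine synthesis (chromosome 10, 40287458 to 40302186), was 1638 ± 199 CPM (SD, n = 4) in male and 205 ± 8.77 CPM (SD, n = 3) in female wild type chow. Amd2 and Amd-ps3 are copies of Amd1, so reads may be divided among them. On the sex chromosomes Xist (9.08 ± 0.23), Chrdl1 (1.30 ± 0.20), Xpnpep2 (1.29 ± 0.19), Tnmd (1.11 ± 0.18) and Car5b (1.09 ± 0.17) were higher in females, and Ddx3y (-10.07 ± 0.22), Eif2s3y (-9.80 ± 0.17), Kdm5d (-9.08 ± 0.23), Uty (-7.84 ± 0.20) and the X-linked Wnk3 (-0.79 ± 0.15) lower.

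Of 13 polyamine genes 7 were lower and 2 higher in females, with Odc1 at -1.70 ± 0.10 and Smox at -2.06 ± 0.12, the same numbers adjusted over the list alone, and adjusted p = 0.117 with an estimated correlation. Of 35 matrix genes 29 were higher, with Col1a1 at 1.39 ± 0.19 and Lum at 1.12 ± 0.14, and 32 adjusted over the list alone, with adjusted p = 0.214 with an estimated correlation. Of 15 tendon markers 12 were higher, with Cilp2 at 1.74 ± 0.14 and Comp at 1.63 ± 0.14, and 12 adjusted over the list alone, with adjusted p = 0.157 with an estimated correlation. Of 17 slow-fibre genes 12 were higher, with the slow myosin gene Myh7 at 1.21 ± 0.20 and Tnnc1 at 1.08 ± 0.20, and 13 higher and 1 lower adjusted over the list alone, with adjusted p = 0.286 with an estimated correlation. Of 15 fast-fibre genes 7 were lower, with Myoz1 at -0.51 ± 0.07 and Myh4 at -0.36 ± 0.07, and 7 adjusted over the list alone, with adjusted p = 0.513 with an estimated correlation. Of 17 adipocyte markers 12 were higher, with Cfd at 1.79 ± 0.15 and Plin1 at 1.52 ± 0.20, with adjusted p = 0.208 with an estimated correlation. With the tendon score of each library as a further term 229 genes were called for sex, while errors grew 2.2-fold. The count was 550, 579, 810 and 1088 with the fibroblast, adipocyte, macrophage and matrix scores. Slow-fibre, endothelial and oxidative phosphorylation scores gave 2466, 2835 and 4603. For many of these genes a different share of tendon or other tissue in the samples and a sex difference cannot be told apart. The sex count was 2944 without the 3 libraries high in Krt10.

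In wild-type mice on chow alone, 1390 genes differed by sex, 675 higher and 715 lower in females (n = 4 and 3). Mup10 (5.41 ± 0.79), Adgrb2 (3.42 ± 0.36), Sfrp2 (3.29 ± 0.51), Adrb3 (3.19 ± 0.46) and Cfd (3.02 ± 0.30) were highest, and Actr3b (-3.74 ± 0.22), Slc15a5 (-3.46 ± 0.57), Odf3l2 (-3.18 ± 0.33), Slc30a2 (-3.10 ± 0.21) and Amd1 (-3.00 ± 0.16) lowest. Of 15 tendon markers 12 were higher, with Comp at 2.39 ± 0.27 and Chad at 2.53 ± 0.31, and of 13 polyamine genes 7 were lower. Both calls held, with adjusted p = 0.0317 with an estimated correlation. Of 36 fatty acid oxidation genes 15 were lower in females, with Acot2 at -1.61 ± 0.17 and Pdk4 at -2.13 ± 0.42, and 23 adjusted over the list alone, with adjusted p = 0.284 with an estimated correlation. Without female wild type chow 4 the called genes were 3 for fatty acid oxidation and 8 for tendon. With the tendon score as a further term 32 of all genes were called for sex. Macrophage, adipocyte and fibroblast scores gave 290, 316 and 344, and the endothelial score 2404. The count was 407, 680 and 859 without female wild type chow 4, male wild type chow 4 and male wild type chow 2, 351 without the 3 libraries high in Krt10, 142 with all 31 libraries grouped by title, and 855 in a fit to these 2 groups alone. Slc15a5 turned to 1.503 with all 31 libraries grouped by title, which puts a library with Ddx3y at 34.05 CPM among female wild type chow.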

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

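The tests of another tissue's share and of moved titles were chosen after the results were seen, and so were the corrections for GC content and length and the scale near Trim63 without 4 libraries.

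The sex-by-diet interaction drew attention because 6206 genes differed between the sexes in their diet effect, among them Chrna2 (3.86), Acot1 (3.84), Pdk4 (3.38), Cidea (3.14), Angptl4 (3.06), Mup10 (-6.71), Dmkn (-6.25), Cyp2e1 (-5.49), Sfrp2 (-4.14) and Pon1 (-4.09). In 1 of 40 splits of the libraries, the real one, as many genes were called, and the highest other count was 2388. These splits exchange sex and diet labels together within each genotype. They also break up the sex difference, which then adds to the spread, so they do not test the interaction alone. Wild-type and knockout libraries, which share none, had correlated interaction values (Pearson's r = 0.702), which argues against 1 genotype alone. After corrections for GC content and for length, 66.1% and 72.5% of the genes were still called with the same sign, between the bounds of 50% and 75% set beforehand, so a part played by either stays open. With the tendon score of each library as a further term, chosen as the strongest of 8 single scores and with bounds written after its result was known, 127 genes were called and the slope on the original values was 0.529, while errors grew 1.86-fold and 87.5% of the score's variance lay between groups, so a different share of tendon in the samples and a sex-specific diet response cannot be told apart.

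With the other scores as the term the interaction was called for 1020 (oxidative phosphorylation), 1403 (macrophage), 2362 (extracellular matrix), 2434 (fibroblast), 4675 (slow fibre), 4803 (adipocyte) and 6590 genes (endothelial), and for 93 with adipocyte, macrophage and tendon scores combined. With the tendon score Pdk4 went from 3.38 to 3.25 (adjusted p = 0.0531), Angptl4 from 3.06 to 3.26 (adjusted p = 0.039) and Cyp2e1 from -5.49 to -3.94 (adjusted p = 0.0154) in edgeR, and the median of the fatty acid oxidation genes from 0.79 to 0.70. The same score left 229 genes for sex on average and 32 for sex in wild type chow. Diet gave 57, 106, 103 and 10 in wild-type males, knockout males, wild-type females and knockout females, against 65, 1618, 2101 and 2758 without it. For diet in knockout males the fibroblast, macrophage and matrix scores left 18, 25 and 43 genes, fewer than the tendon score. Slow-fibre and adipocyte scores left 546 and 1295 there. Apart from diet in wild-type males, a part played by the share of tendon or other cell types stays open in these comparisons too.

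The labels of 5 libraries drew attention because their sex or genotype genes go against a title. Among the 4 libraries in no group, the one titled female wild type chow held Ddx3y at 34.05 CPM and Trim63 at 1.8 CPM, and those titled female knockout chow, female wild type high fat and female knockout high fat held Trim63 at 221.42, 0.87 and 119.2 CPM. In 3 of 4 these levels go with the group of the animal number in the description, as titles moved by 1 position against the count files would give. The library with 119.2 CPM lies near the lower end of the range of wild-type labels (108.54 to 253.61 CPM). It lies far above 12 knockout libraries (at most 6.24 CPM), which goes against its title. As a library with 107.11 CPM carries a knockout label, the genotype at this level is not settled, so moved titles stay open. The library labelled male knockout high fat replicate 1, with Trim63 at 107.11 CPM, lay at 0.559 on a scale of the other changed genes near Trim63, where 13 libraries with Trim63 from 183.3 to 253.61 CPM ran from -0.248 to 0.152. With genes and ends chosen without the 4 libraries of Trim63 between 50 and 150 CPM it lay at 0.576 (95% interval 0.447 to 0.721 over genes), above the bound of 0.35 set beforehand, which argues against a wild-type library like those 13, whose scores were at most 0.221. A heterozygous animal or a mixture of wild-type and knockout RNA may account for it, and the other 3 of the 4 had scores of 0.418 (male wild type chow 3), 0.446 (female wild type chow 2) and 0.51 (titled female knockout high fat), below 14 libraries with Trim63 of at most 6.24 CPM (0.635 to 1.225). No genotype from DNA was used here, so the genotype of these 4 stays open. No biological explanation was tested.

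The difference in the genotype effect between diets was called for 3 genes, Mid1ip1 (-1.49), Lmod2 (-0.997) and Hspb7 (-0.965), where 2 of 40 splits gave as many and the highest other gave 81, which points to a structure of the samples, so chance is not excluded. The difference between sexes was called for 1 gene, Adgrb2 (-2.75), where 3 of 40 splits gave as many and the highest other gave 7, so chance is not excluded. Male wild type chow replicate 2 stood apart from its group with a neutrophil and mast cell score of 0.645 against 0.974 for the nearest other library. Male wild type high fat replicate 2 stood apart with a total of 9.3 M counts (9342028) against 12.0 M for the nearest other library. These 2 came from 42 such tests, where about 1 in 20 is found by chance.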

How the results depend on the processing

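The corrections for GC content and length, the 30 libraries by animal number, and the omission of keratin-high libraries and of libraries with Trim63 between 50 and 150 CPM were chosen after the data were seen. Totals of 9342028 to 14919379 counts per library limit what can be said of genes under 1 CPM. Unless a reason is given, the cause of a change was not tested. The number of called lists was 0 for genotype, 0 for diet and 0 for sex on average with an estimated correlation in camera, and 7, 0 and 23 with fry. For genotype fry called 14 lists in male chow and 0, 0 and 0 in male high fat, female chow and female high fat. For diet it called 0, 15, 5 and 13 in wild-type males, knockout males, wild-type females and knockout females. It called 6 for sex in wild type chow, 22 for sex by diet, and 0 and 0 for genotype by diet and by sex. With DESeq2 size factors genotype in female chow gave 0 genes (522 at unadjusted p under 0.05 in edgeR, 11 by the DESeq2 Wald test) and the genotype-by-diet interaction 5. The DESeq2 Wald test gave 54, 11 and 194 genes for genotype in male high fat, female chow and female high fat, 327 and 167 for diet on average and in wild-type males, 46 and 16 for genotype by diet and by sex, and Trim63 at -7.26 in female chow (adjusted p = 2.55e-07). Without a count filter diet on average gave 86 genes, genotype by diet 1 and genotype by sex 5. With a filter of 1 CPM in 50% of the libraries, which tests fewer genes, genotype in female chow gave 0, genotype by diet 5 and genotype by sex 0.

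Grouping by title places a library with Ddx3y at 34.05 CPM among females. It also places a library with Trim63 at 221.42 CPM among knockouts and a library with 0.87 CPM among wild types. With all 31 libraries grouped by title, genotype gave 134 genes on average and 501 in male chow, and 0, 0 and 0 in male high fat, female chow and female high fat (1021, 587 and 1856 at unadjusted p under 0.05 in edgeR). Diet gave 0 on average (1529 unadjusted) and 1, 995 and 5 in wild-type males, knockout males and wild-type females, sex in wild type chow 142, and genotype by diet and by sex 0 and 0 (800 and 1182 unadjusted). Trim63 was -6.20 in male chow (adjusted p = 0.0934) and -2.31 in female high fat (adjusted p = 0.547), 8 lists were called for diet on average, and Slc15a5 turned to 1.503 for sex in wild type chow. With all 31 grouped by animal number, genotype gave 32, 10 and 9 in male high fat, female chow and female high fat, diet 207 on average and 3656 in wild-type females, genotype by diet 22 and by sex 3, and Trim63 -7.44 in female chow (adjusted p = 0.0107). With 30 libraries by animal number, which leaves out male knockout high fat 1, the same results were 38, 16, 10, 116, 3562, 15 and 5, diet in knockout males 789, Trim63 -7.70 in male high fat (adjusted p = 1.65e-08) and -7.44 in female chow (adjusted p = 2.4e-09), and Trim63 for diet in knockout males turned to -1.29.

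In fits to the compared groups alone, genotype gave 306 in male chow, 8 in female chow and 12 in female high fat, diet 3188, 743 and 1514 in knockout males, wild-type females and knockout females, sex in wild type chow 855, and Trim63 -7.25 in female chow (adjusted p = 6.97e-05). Without genes within 10 Mb of Trim63, genotype gave 7, 0 and 0 in male high fat, female chow and female high fat (491 and 1907 unadjusted in the females), a setting that tests fewer genes. After GC correction genotype gave 0 in female chow (587 unadjusted) and 12 in female high fat, and diet 2, 98 and 140 on average, in wild-type males and in wild-type females. After GC and length correction these were 9 in female high fat, 9, 161 and 209 for diet, 1716 for genotype in male chow and 2 for genotype by sex. After length correction, genotype in female high fat gave 61, diet in wild-type males 104, genotype by diet 5 and by sex 2. Without the 3 keratin-high libraries, which leaves 1 female knockout chow library assumed to vary like the other groups, genotype gave 85 on average, 0 in female chow (238 unadjusted) and 17 in female high fat, with Trim63 at -7.56 (adjusted p = 0.059), diet 2, 321 and 3 on average, in wild-type females and in knockout females, sex 2944 on average and 351 in wild type chow, and the interactions 1 for genotype by diet and 3901 for sex by diet. Without the 3 libraries with Trim63 between 50 and 150 CPM, which leaves 2 each of male knockout high fat and female wild type chow, genotype gave 290 in male chow and 17 in female chow, diet 2 on average, 648 in knockout males and 848 in wild-type females, Trim63 -8.251 in male high fat (adjusted p = 3.38e-07) and -7.428 in female chow (adjusted p = 1.76e-07), and Trim63 for diet in knockout males turned to -1.853.

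Leaving out 1 library at a time gave 317 to 1164 genes for genotype on average, 224 to 1852 in male chow, 6 to 83 in male high fat, 0 to 17 in female chow and 3 to 34 in female high fat. Diet gave 25 to 335 on average, 22 to 62 in wild-type males, 375 to 2229 in knockout males, 150 to 2772 in wild-type females and 414 to 3208 in knockout females. Sex gave 4041 to 5166 on average and 407 to 1595 in wild type chow, and the interactions gave 0 to 37 for genotype by diet, 1 to 57 for genotype by sex and 5445 to 6558 for sex by diet. Lists called were 12 to 18 for genotype, 7 to 16 for diet and 19 to 23 for sex. Trim63 ran from -7.36 to -5.81 in male chow, -8.23 to -2.08 in male high fat, -7.50 to -7.08 in female chow and -7.71 to -7.33 in female high fat, and for diet in knockout males it ran from -1.85, without male knockout high fat 1, to 4.84. Replicate numbers did not pair libraries. Residuals of 83 pairs with the same number had a mean correlation of -0.001 against 0.001 for 235 other pairs, and 8 of 27 libraries correlated best with their own number. A block by replicate number gave 576 genes for genotype, 46 for diet, 4209 for sex and 6116 for sex by diet on average.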

Other observations

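The tests of strain DNA and of a local effect around Trim63 were chosen after the results were seen.

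Diet effects were also compared between groups over all genes. The log2 fold changes of the diet correlated between wild-type and knockout females (Pearson's r = 0.686), and of 1016 genes called in both, 1015 had the same sign, where 212 are expected from independent calls. In males the correlation between genotypes was 0.351, with 34 of 34 shared calls in the same direction. Between females and males it was -0.238 in wild types, with 18 of 19 shared calls opposite, and -0.503 in knockouts, with 714 of 719 opposite. Xist was lower in females on the high-fat diet (67.65 to 143.88 CPM in 6 libraries) than in females on chow (205.49 to 270.88 CPM in 6 libraries). These CPM are not corrected for transcript length. Mean slopes with length (log2 per doubling) were -0.044 and -0.068 in female wild type and knockout high fat, and 0.059 and 0.081 on chow. A length bias in the Xist values was not tested.

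Genes called by the average genotype contrast were enriched around Trim63 on chromosome 4. The enrichment at 2 to 25 Mb (odds ratio 3.89, lower 95% bound 2.91) argues against an effect on direct neighbours alone. DNA of another strain carried along with the targeted allele may account for it. Of 23 called genes off chromosome 4 with a 2-fold change, 4 (17.4%) had their closest copy within 25 Mb of Trim63, against 1 of 300 random genes (Fisher's exact test, two-sided, p = 9.47e-05). Reads of chromosome 4 genes counted on copies could explain those 4. Among them are Eno1b (2.18, with Eno1 at -0.39) and BC002163 (3.84, with Ndufs5 at -1.02). An effect of MuRF1 loss on genes of this region stays open, as the design has no other strain or allele.

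Over the 15 comparisons, other splits of the same libraries were counted, the real one included. As many genes were called in 1 of 40 splits for genotype on average (737, highest other 2), diet on average (57, highest other 29) and sex on average (4738, highest other 973). The same held in 1 of 35 for diet in wild-type males (65, highest other 2), diet in knockout males (1618, highest other 1357) and sex in wild type chow (1390, highest other 736). These shares lie under 0.05 and are the smallest that so few splits can give. They were not adjusted over the 15 comparisons, so chance is less likely but not excluded. For the averages the labels were exchanged within strata, which also breaks up effects that differ between strata and adds them to the spread. Diet effects were opposite between the sexes for many genes, so for diet on average these splits do not test the average alone and cannot decide. The split with 1357 sets knockout chow 1, 2 and 3 against chow 4 and the 3 high-fat libraries, so it differs from the real one by chow 4 alone. It is therefore not free of the diet difference, and without knockout chow 4 the real comparison called 2229. For genotype in male chow 2 of 35 splits gave as many, and the one that exchanges wild type 4 and knockout 4 gave 1528 against the real 1011. For genotype in male high fat 2 of 35 splits gave as many, with 81 against 19. That split sets wild type 1, 2 and 3 against wild type 4 and the 3 knockouts, so it differs from the real one by wild type 4 alone. It is therefore not free of the genotype difference, and without wild type 4 the real comparison called 83. In both male strata the splits do not exclude chance. The 10 splits of 3 against 3 libraries are too few for a share under 0.05. The real and highest other counts there were 5 and 36 for genotype in female chow, which points to a structure there, 34 and 1 in female high fat, 2101 and 2 for diet in wild-type females, and 2758 and 0 in knockout females by edgeR.

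Keratin and other skin genes were high in female wild type chow 4 and female knockout chow 2 and 4, with Krt10 at 23.75, 22.38 and 47.38 CPM. S100a8, a neutrophil and skin gene, stood at 27.52 CPM in female knockout chow 2 and at 24.35 CPM in the library in no group that is titled female knockout chow. GC slopes per library were highest in female wild type high fat (mean 0.339, range 0.106 to 0.666). Fold changes correlated with transcript GC content for diet on average (Spearman's rho = 0.576), diet in knockout females (0.399), the sex-by-diet interaction (0.437) and genotype on average (-0.348). With transcript length Spearman's rho was -0.322 and -0.418 for diet in wild-type and knockout females and -0.392 for the sex-by-diet interaction. Mitochondrial genes held 5.4% of counts in female wild type high fat 4 and 5.55% in female knockout high fat 3, the lowest of the 31 libraries.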
